A study of Mus musculus with 10 samples.

How the data were processed

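The study measured mRNA of whole testes from mice at postnatal day 10, with 5 wild-type and 5 FXRα-null (Nr1h4) mice. Per the labels' protocols, frozen testes were extracted with Trizol and libraries were made from total RNA with an Illumina TruSeq RNA kit, and per the series' design text all were sequenced on 1 flowcell and each library came from an individual mouse. Per the submitters' processing notes, the tools FastQC 0.10.1, CASAVA, Bowtie, TopHat2 2.0.10 and Bowtie2 2.1.0 and the genome build mm10 were used, with no role or order given. The read counter, the annotation release, the use of strand and the treatment of reads with several alignments are not given in the sources used here. The deposited table held raw counts per gene for each library, and these whole-number counts, as made by the authors, were the input of every main test. The same deposited table held other values, the authors' normalized expression, whose decimal marks had been lost. Each library's scaling factor was recovered from the digits of these deposited values (100.0% of genes with over 1000 counts matched, within 0.0001 on the log10 scale), and they served only in an alternative. Values per kilobase in the table were not used here. No column belonged to other samples.

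The table held 30719 genes, none without a read in all libraries, and 30212 were matched by Ensembl identifier to GENCODE M21 on GRCm38, the same build as mm10, for positions and gene types. The 507 unmatched genes held 0.200% of counts and stayed in the tests without a position. Gene symbols that a spreadsheet had turned into dates (28) were replaced through the identifier. Samples were grouped by the genotype in the labels, and their titles' numbers name the libraries (wild type 3, 4, 5, 6 and 9, knockout 8 to 12). The strain labels carry a number that runs on from sample to sample and were not used. Depth was 32330029 to 39655170 counts per library. Where a gene had no count in a group, 3 counts per library were taken as its floor.

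Genes were filtered with filterByExpr, scaled with TMM factors and tested with edgeR 4.0.16 (quasi-likelihood F-test, two-sided, Benjamini-Hochberg adjustment over 18559 genes) in R 4.3.3, with genotype as the only term. Adjusted p-values of genes in the text come from this test, a gene was called changed under an adjusted p of 0.05, and log2 fold changes are knockout over wild type. The same design, the lists and the alternatives were fixed before the data were examined, except where the text says otherwise. A total of 29 gene lists (658 entries, of which 610 were tested) covered germ, Sertoli, Leydig, interstitial, immune, vascular, blood, fat, duct and muscle cells, FXR targets and metabolic and stress pathways. Members of each list were also adjusted over the list alone. Lists were tested with camera at a preset correlation of 0.01 between genes, with the correlation estimated per list, and with fry (limma 3.58.1). The mean log2 CPM (prior count 2) of each list was compared between mice in an exact two-sided permutation test over 252 assignments, adjusted over the lists. Of the 29 lists, 12 passed by camera, 0 held with an estimated correlation, 2 passed by fry and 0 passed by the test over mice, whose smallest adjusted p was 0.115. With 252 assignments the test over mice cannot give a p below 0.00794. After adjustment over the 29 lists, a list on its own could therefore not pass it, and its 0 does not argue against a change in a single list.

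Named genes were chosen by a rule. It took the 12 largest rises and the 12 largest falls among changed genes with a mean of at least 1 CPM, no overlap between the genotypes and a name that is neither a numbered model nor a pseudogene, Nr1h4 in every case, and up to 4 changed members per list with the smallest p, or the 2 most abundant where none changed. Some genes picked by the rule are not reported here. Genes outside the rule were named after their values were seen and are marked so, except members of the Sertoli list, given to complete its count. Chromosomes were compared with one-sided Fisher's exact tests and the surroundings of Nr1h4 with a two-sided one (scipy 1.17.1). Gene Ontology terms in the deposited table with 10 to 500 tested genes were tested after the main results were seen, with one-sided Fisher's exact tests among tested genes that carry a term of that ontology.

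The edgeR test, camera and the test over mice were run on simulated counts drawn from the real libraries' means and sizes, and the chromosome and Gene Ontology tests on simulated calls. Among 18382 simulated genes, the edgeR step recovered 7.69% of genes changed 1.2-fold, 69.0% of genes changed 1.5-fold and 88.4% of genes changed 2-fold, and 3.39% of its calls were false. Simulated changes of 1.2-fold were therefore mostly missed. Few genes were changed in the simulation (65, 29 and 69 at these folds, besides a list raised for camera), against 2576 called in the data. Its adjusted threshold was therefore stricter, and these shares do not carry over to the data. Alternatives covered other scalings, DESeq2 1.42.0, limma-voom, other filters and thresholds, and leaving out each library. Each library came from another mouse, so p-values judge a difference against the spread between individual animals within the genotypes. The labels give no litter, so litters or breeding lines that differ between the genotypes cannot be told apart from genotype. The titles do not pair wild-type with knockout mice, since only the number 9 occurs in both groups.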

Results

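Testis RNA was profiled by RNA sequencing in mice at postnatal day 10, when the tubules hold spermatogonia, the first meiotic cells and immature Sertoli cells. Wild-type mice were compared with mice lacking FXRα, the farnesoid X receptor, a nuclear receptor activated by bile acids and encoded by Nr1h4. Each genotype was represented by 5 individual mice, with 1 library per mouse and all libraries on 1 flowcell, and the mice were of a mixed 129sv and C57Bl background. The comparison asked which testicular transcripts differ in the absence of the receptor. The libraries held 32330029 to 39655170 counts, with 33746395 ± 950796 in wild type and 37089682 ± 2529431 in knockout (SD, n = 5 each). Mitochondrially encoded genes took 1.88 ± 0.0714% of counts in wild type and 2.23 ± 0.162% in knockout (SD, n = 5 each). Across genes, which are not independent replicates, log2 CPM (counts scaled to a common library size) correlated at 0.989 to 0.994 within wild type, 0.988 to 0.995 within knockout and 0.981 to 0.987 between the genotypes. The first principal component held 41.3% of the variance and separated all 5 knockout from all 5 wild-type libraries. The second held 13.8% and spread the libraries within both genotypes.

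Nr1h4 itself (ENSMUSG00000047638, GRCm38 chromosome 10, 89454234 to 89533585, minus strand) was expressed close to the detection limit in both genotypes. Wild-type libraries 3, 4, 5, 6 and 9 held 15, 15, 13, 14 and 26 counts, and knockout libraries 8 to 12 held 8, 9, 11, 11 and 13 counts. The means were 16.6 ± 5.32 counts in wild type and 10.4 ± 1.95 in knockout (SD, n = 5 each). Nr1h4 was lower in knockout testis by edgeR's quasi-likelihood test (log2 fold change -0.84, SE 0.234, adjusted p = 0.0347), with no overlap between the genotypes in CPM, although wild-type library 5 and knockout library 12 tied in counts (exact two-sided permutation p = 0.00794, the smallest that 252 assignments can give). The call did not survive DESeq2 (adjusted p = 0.0658) or the removal of any of 7 single libraries, where the log2 fold change ranged from -0.92 to -0.62. The labels do not say which part of the gene was removed, so the remaining reads may or may not lie outside it, and the depth at this gene limits what it can say about the labels.

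Absence of FXRα was accompanied by many small changes and a short series of large ones. Rxfp1, the receptor for the hormone relaxin, rose 53.8-fold, from 0.583 ± 0.122 to 31.5 ± 5.36 CPM. Slc39a8, a zinc and manganese transporter, rose 5.97-fold, from 4.60 ± 0.494 to 27.5 ± 2.21 CPM. In the opposite direction, Olfml3, which encodes a secreted olfactomedin-like protein, fell from 67.3 ± 3.10 to 16.2 ± 1.67 CPM (SD, n = 5 each). In all, 2576 of 18559 tested genes changed at an edgeR adjusted p under 0.05, of which 1146 rose and 1430 fell. The median size of these changes was 0.36 on the log2 scale, and 718 genes changed at least 1.5-fold, with 498 higher and 220 lower. In 2146 of all tested genes (11.6%) the 5 knockout values did not overlap the 5 wild-type values, against 0.794% by chance, and 1772 of these genes were among the changed ones, which the test had picked for their separation. The split between rises and falls depended on the scaling, since 44.5% of changed genes were higher with trimmed-mean scaling, 53% with upper-quartile scaling and 61.5% with library totals alone. The number of changed genes dropped to 1427, 1601 and 1635 without knockout library 11, wild-type library 4 and knockout library 12. Of all 2576 calls, 54.4% were kept without knockout library 11 and 59.4% without wild-type library 4. Besides Nr1h4, 105 changed genes were picked by the naming rule, and 77 of these kept their call whichever single library was left out. The rule picked them from the same fit, by small p or lack of overlap, so this share does not stand for all changed genes.

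**Figure D1:**
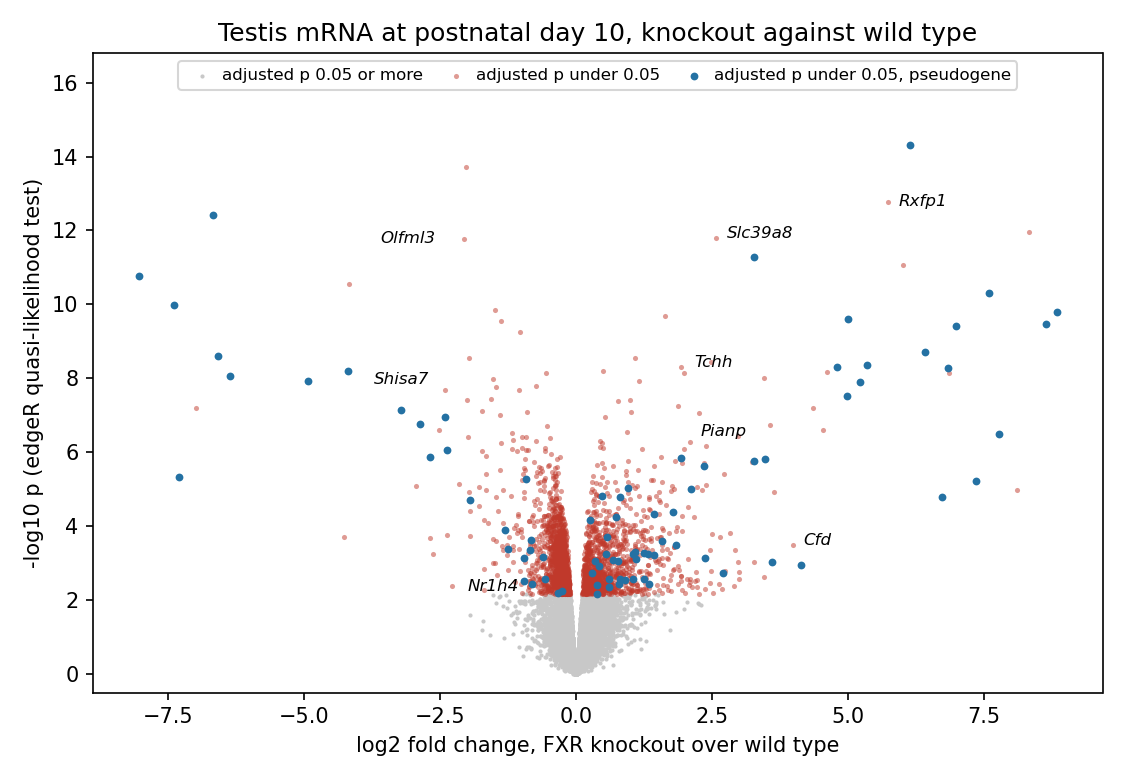
Change in each of 18559 tested genes, with the log2 fold change of knockout over wild type on the horizontal axis and -log10 of the edgeR p-value on the vertical axis. Most coloured points, the 2576 genes past an adjusted p of 0.05, lie within a narrow band around 0, while pseudogenes (blue) make up 19 of the 25 changed genes whose fitted change is at least 32-fold.

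The 12 largest rises among named genes with at least 1 CPM and no overlap between genotypes ranged from 3.98-fold to 53.8-fold. After Rxfp1 they were Cfd (15.9-fold), Tshr (7.93-fold), Ros1 (7.12-fold), Slc39a8, Tmod4 (5.58-fold), Cfi (5.27-fold), Crxos (5.14-fold), Lpl (4.97-fold), Selenbp2 (4.78-fold), Pianp (4.29-fold) and Tchh (3.98-fold). Cfd and Lpl, which encode adipsin and lipoprotein lipase, are abundant in fat cells, and Tshr encodes the thyrotropin receptor. Ros1 is a member of the epididymis and rete testis list. With that list's value as a covariate, which itself separates the genotypes, the log2 fold change of Ros1 was -0.14. Tshr, at a log2 fold change of 2.99, lost its edgeR call without knockout libraries 9 and 10 (1.70, adjusted p = 0.0513) and with the adipocyte value of each library as a covariate (0.73, adjusted p = 0.125), both chosen after seeing the data. Ros1 and, among the falls below, Abca17, Slc2a2 and Dynlt1a also lost their calls with the adipocyte covariate. The 12 largest falls ranged from 2.89-fold to 6.15-fold and included Abca17 (6.15-fold), Shisa7 (5.32-fold), Rimbp2 (4.42-fold), Olfml3 (4.16-fold), Lair1 (3.92-fold), Slc2a2 (3.86-fold), Traf1 (3.33-fold), Guca1b (3.21-fold), Dynlt1a (3.07-fold), Usp44 (2.94-fold) and Zfp872 (2.89-fold). The log2 fold change of Abca17, -2.62 in all libraries, ran from -3.93 to -2.37 when 1 library was left out. Knockout library 8 stood apart in this gene (1.63 log2 CPM, other knockouts -1.81 to -1.02). Slc2a2 encodes the glucose transporter GLUT2, and Traf1 a signalling adaptor of tumour necrosis factor receptors. By edgeR the adjusted p of the genes given here lay between 1.05e-09 (Rxfp1) and 0.0204 (Guca1b). Guca1b lost its call without knockout library 11 (adjusted p = 0.0554 by edgeR). Dynlt1a has near-identical neighbouring copies and Crxos lies opposite another gene, so their values are uncertain because reads may be shared. Of the 24 genes with the largest changes, 8 lie on chromosome 3 (Rxfp1, Slc39a8, Tmod4, Cfi, Selenbp2, Tchh, Olfml3 and Slc2a2). That chromosome holds 4.66% of all tested genes with a mean of at least 1 CPM and no model or pseudogene name, whether changed or not.

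**Figure D2:**
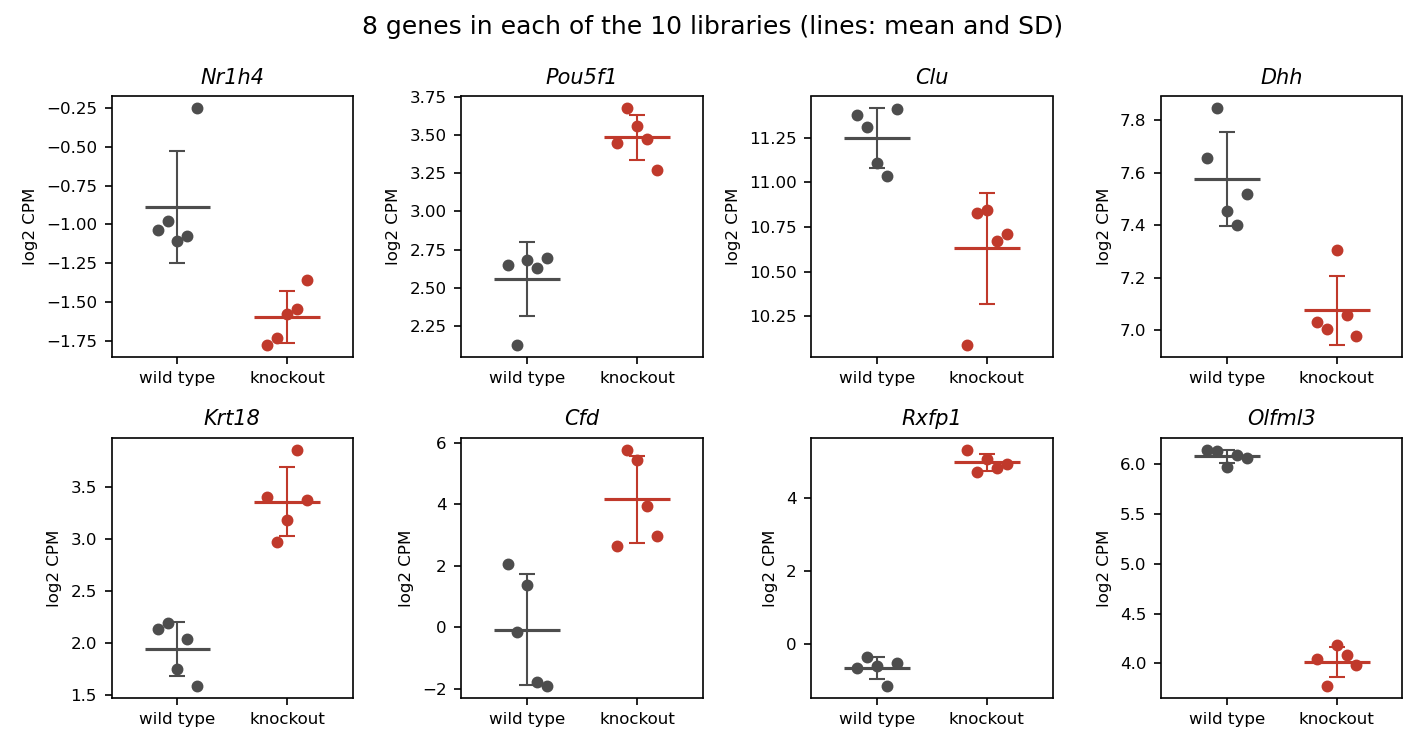
Expression of 8 genes as log2 CPM in each library, with 5 wild-type (grey) and 5 knockout (red) points per gene, horizontal lines at the mean and bars of 1 SD. The groups do not overlap in any of the 8 panels, and the fitted log2 fold change runs from -2.06 for Olfml3 to 5.75 for Rxfp1.

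Germ cell genes that changed lay in several lists, and no gene of the meiotic prophase list passed. Pou5f1, the pluripotency factor that marks early spermatogonia, rose 1.90-fold, from 5.89 ± 0.891 to 11.2 ± 1.16 CPM (SD, n = 5 each), with an edgeR adjusted p of 0.000566. Among 19 measured pluripotency factors, Pou5f1, Tfcp2l1 (1.46-fold) and Nanog (1.56-fold) rose and 16 did not pass, with 3 past the test when adjusted over the list alone. Nanog lay near 1 CPM and lost its call without any 1 of 4 libraries (wild-type 4 and 6, knockout 11 and 12; edgeR adjusted p up to 0.0602). Of 26 genes of undifferentiated spermatogonia, Pou5f1 and Upp1 rose, Ccnd2 and Etv5 fell, and 22 did not pass (4 adjusted over the list alone). Etv5, a transcription factor of spermatogonial self-renewal, fell 1.26-fold with an edgeR adjusted p of 0.0487, which was lost in 17 of 24 alternatives, 7 of them without a single library. Of 20 genes of differentiating spermatogonia, 5 rose and 15 did not pass (5 adjusted over the list alone), and the risers included Sohlh1 (1.26-fold) and Sohlh2 (1.27-fold), transcription factors of spermatogonial differentiation, Mageb4 (1.24-fold) and Ccnb1ip1 (1.53-fold). The whole list was higher by camera (adjusted p = 0.000936), but not with an estimated correlation between its genes (adjusted p = 0.737 with an estimated correlation). Its mean log2 CPM was 0.264 higher in knockout (exact two-sided permutation p = 0.151), and 0.139 higher without wild-type library 3. Sohlh1 and Ccnb1ip1 lost their calls when single libraries were left out (edgeR adjusted p up to 0.0657 and 0.0538).

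None of 36 meiotic prophase genes passed the test (0 adjusted over the list alone), while 32 had a fitted change above 0 (median 0.24). Tex15, needed for meiotic recombination, stood at 327 ± 125 CPM in wild type and 336 ± 92.3 in knockout, and the cohesin subunit Stag3 at 210 ± 48.9 and 249 ± 44.7 CPM (SD, n = 5 each). Camera placed the meiotic list higher in knockout (adjusted p = 0.0142), but not with its estimated correlation (adjusted p = 0.795 with an estimated correlation). Within wild type the mean log2 CPM of this list ran from 3.87 in library 3 to 4.98 in library 6, against a difference between genotypes of 0.27 (exact two-sided permutation p = 0.325). Without wild-type library 3 this difference was 0.095 and the camera call was lost (adjusted p = 0.309). Of 21 measured pachytene and spermatid genes, 4 rose and 2 fell (6 adjusted over the list alone). Ccna1, the germ cell cyclin A1, rose 2.60-fold, the chaperone gene Clgn 1.54-fold and Zpbp 1.30-fold, while Meig1 fell 1.48-fold. Calr3 rose and Piwil1 fell as well, named after their values were seen. Of 17 pan-germ cell genes, Asz1 (1.25-fold) and Mael (1.21-fold) rose and 15 did not pass (4 adjusted over the list alone; camera adjusted p = 0.00175, adjusted p = 0.737 with an estimated correlation). The mean log2 CPM of the pan-germ cell list was 0.216 higher in knockout (exact two-sided permutation p = 0.0714), and 0.138 higher without wild-type library 3. Asz1 and Mael, which act in the control of transposons by small RNAs, were also those that rose among 19 genes of germ-line methylation and transposon control (6 adjusted over the list alone, of which 3 were higher and 3 lower).

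Changes among Sertoli cell genes were mostly falls. Of 33 measured members, 12 fell, 1 rose and 20 did not pass, and 20 passed when adjusted over the list alone. Clu, which encodes the abundant secreted protein clusterin, fell from 2445 ± 276 to 1613 ± 305 CPM, the anti-Müllerian hormone receptor gene Amhr2 from 310.8 ± 28.3 to 218 ± 24.8 CPM, and the hedgehog ligand gene Dhh from 192 ± 24.7 to 135 ± 13 CPM (SD, n = 5 each; edgeR adjusted p = 0.0108, 0.003 and 0.00418). Sox9, Sox8, Wt1, Gja1, Inha, Inhbb, Nr0b1, Rhox8 and Aard also fell, by 1.16-fold to 1.38-fold. Cst9 was the exception and rose 1.69-fold, from 197 ± 23.9 to 333 ± 62.4 CPM (SD, n = 5 each). The list was lower by camera (adjusted p = 7.59e-07), but not by camera with its own correlation (adjusted p = 0.737 with an estimated correlation). Its mean log2 CPM was 6.82 ± 0.095 in wild type and 6.55 ± 0.176 in knockout (SD, n = 5 each; exact two-sided permutation p = 0.0317, adjusted over the 29 lists 0.115). Knockout library 8 had the lowest Sertoli value at 6.31, and without it the difference went from -0.27 to -0.21.

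Genes of the Sertoli barrier and of androgen action moved in the same tissue in both directions. Of 22 measured blood-testis barrier junction genes, 8 fell and 4 rose (18 adjusted over the list alone). The junction scaffold gene Tjp1 (1.13-fold) and the tight junction protein gene Ocln (1.34-fold) fell, while Cldn3, which encodes claudin 3, rose 1.68-fold. Dsg2, Gjc1 and Marveld3 were the other junction genes that rose, named after their values were seen. Of 16 androgen-responsive Sertoli genes, Serpina5 (1.71-fold), Tubb3 (1.64-fold) and Osr2 (1.25-fold) fell, Cldn3 rose and 12 did not pass (5 adjusted over the list alone; camera adjusted p = 0.0142, adjusted p = 0.737 with an estimated correlation). Knockout library 8 was lowest in this list too (4.33), and without it the difference in mean log2 CPM went from -0.28 to -0.18. Epididymis and rete testis genes, which include keratins of ductal epithelium, were higher in the same knockout libraries, with a mean log2 CPM of 2.93 ± 0.319 against 1.89 ± 0.238 in wild type (SD, n = 5 each). In the retinoic acid list, Stra6, the membrane receptor for the retinol-binding protein, fell 1.38-fold and Cyp26b1, a retinoic acid-degrading enzyme of somatic cells, 1.23-fold, while 22 of 24 did not pass (2 adjusted over the list alone). The retinoic acid list had a mean change of 0.04 and a median of -0.01, and its camera direction was down (adjusted p = 0.544).

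**Figure D3:**
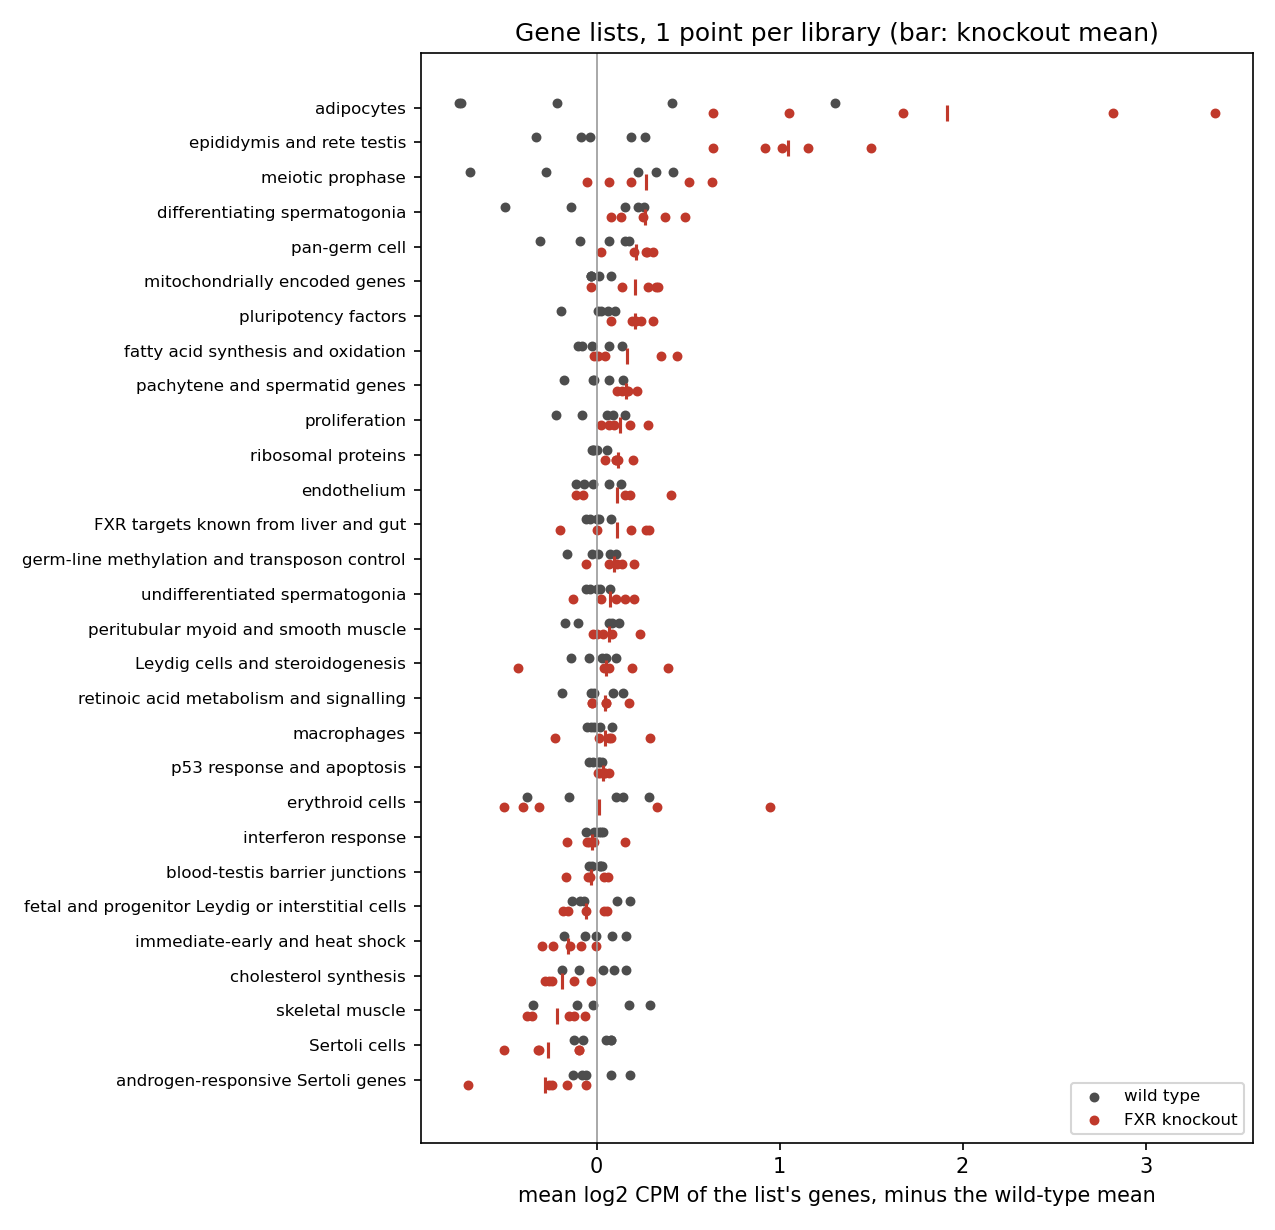
Mean log2 CPM of the genes of each of the 29 lists in each library, as the difference from the wild-type mean, with wild type in grey, knockout in red and a bar at the knockout mean. The adipocyte list (difference 1.91) and the epididymis and rete testis list (1.04) stand apart at the top, and the Sertoli (-0.27) and androgen-responsive Sertoli (-0.28) lists lie at the bottom.

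Many markers of tissues that adjoin the testis were higher in knockout libraries. Of 13 measured epididymis and rete testis genes, 9 rose and 4 did not pass (12 adjusted over the list alone). The keratin genes Krt18, Krt8 and Krt7 rose 2.71-fold, 2.53-fold and 2.56-fold, and Wfdc2 rose 1.81-fold (edgeR adjusted p = 0.000368, 0.00139, 0.00243 and 0.00362). This list was higher by camera (adjusted p = 1.18e-09; adjusted p = 0.421 with an estimated correlation) and its values did not overlap between genotypes (exact two-sided permutation p = 0.00794, the smallest possible). Of 14 measured adipocyte genes, 9 rose and 5 did not pass. Adjusted over the list alone 11 passed, of which 10 rose and 1 fell (Cidea, 1.39-fold, named after its values were seen). Cfd, Car3, Retn and Adipoq rose 15.9-fold, 11.0-fold, 9.72-fold and 8.05-fold, with a large spread between mice, as in Car3 at 16.9 ± 18.9 CPM in wild type and 186 ± 198 CPM in knockout (SD, n = 5 each). The adipocyte values were highest in knockout libraries 9 (5.24) and 10 (4.68), and wild-type library 4 (3.16) lay above knockout libraries 8 (2.49) and 12 (2.91). The camera call of the adipocyte list (adjusted p = 0.000629; adjusted p = 0.737 with an estimated correlation) was lost without knockout libraries 9 and 10 (adjusted p = 0.127), an alternative chosen after seeing the data, as were the edgeR calls of Car3, Retn and Adipoq.

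Other cell types of the interstitium and vessels changed little. Of 20 macrophage genes, Ctss (1.24-fold) and Ms4a7 (1.38-fold) rose (0 adjusted over the list alone). Of 18 endothelial genes, Erg (1.25-fold) and Ecscr (1.24-fold) rose (2 adjusted over the list alone), and of 17 peritubular myoid and smooth muscle genes, Rgs5 rose 1.37-fold and Myl9 fell 1.16-fold (2 adjusted over the list alone). These macrophage and endothelial calls and that of Rgs5 were each lost without any 1 of 5 to 8 libraries (edgeR adjusted p up to 0.0999). Hba-a1, an alpha-globin gene with a near-identical copy and therefore uncertain, was the only 1 of 9 erythroid genes to rise (1 adjusted over the list alone). Ckm, the muscle creatine kinase, was the only 1 of 14 skeletal muscle genes to fall (1 adjusted over the list alone), from 0.525 ± 0.187 to 0.134 ± 0.0326 CPM (SD, n = 5 each).

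Steroidogenic genes did not move one way. Of 22 measured Leydig cell and steroidogenesis genes, 2 rose, 3 fell and 17 did not pass (5 adjusted over the list alone). Nr5a1, the transcription factor SF-1, fell 1.28-fold, the lipoprotein receptor gene Scarb1 1.38-fold and the steroid dehydrogenase gene Hsd3b1 1.36-fold, whereas Hsd11b1 rose 2.73-fold from 1.12 ± 0.152 to 3.05 ± 1.18 CPM (SD, n = 5 each). With the adipocyte value of each library as a covariate, an alternative chosen after seeing the data, Hsd11b1 lost its edgeR call (log2 fold change 0.92 against 1.45, adjusted p = 0.0628). Cyp11b1 also rose, named after its values were seen. The median (0.03) and mean (0.14) of the Leydig list were above 0 and its camera direction was down (adjusted p = 0.572). Of 23 interstitial progenitor genes, 4 fell and 3 rose (9 adjusted over the list alone). The falls included the vascular adhesion gene Vcam1 (1.40-fold), the hedgehog receptor gene Ptch1 (1.34-fold) and Cyp26b1, and Lum, Mc2r and Thy1, named after their values were seen, rose. Of 18 measured genes known as FXR targets in liver and gut, Abcc3, an export pump for conjugated bile acids, rose 2.06-fold, the bile acid transporter subunit gene Slc51a rose 1.88-fold and Scarb1 fell, while 15 did not pass (5 adjusted over the list alone; camera adjusted p = 0.597). Slc51a, at 0.263 ± 0.101 CPM in wild type, lost its edgeR call without any 1 of 8 libraries (adjusted p up to 0.115) and under DESeq2, Hsd3b1 without any 1 of 5 (up to 0.0812), and Scarb1 without knockout library 11 (0.0518). The epididymis and rete testis list was higher in the same knockout libraries (difference 1.04 in mean log2 CPM). With its value as a covariate, also chosen after seeing the data, the log2 fold change was 0.41 for Abcc3 and -0.084 for Slc51a, and neither passed (edgeR adjusted p = 0.613 and 0.972). This covariate itself separates the genotypes, and 60 of all tested genes passed with it. The loss of these calls therefore does not tell duct tissue from a change with genotype.

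Among genes of lipid metabolism more fell than rose, and most did not pass. Of 25 cholesterol synthesis genes, 5 fell, 1 rose and 19 did not pass (7 adjusted over the list alone). Ebp fell 1.41-fold, Dhcr7 1.26-fold and Srebf2, the transcription factor of the pathway, 1.2-fold, and Acat2 rose 1.34-fold. Hmgcs1, named after its values were seen, fell as well. Camera placed the list lower (adjusted p = 0.000629; adjusted p = 0.737 with an estimated correlation), and Srebf2 lost its edgeR call with library totals alone and without any 1 of 4 libraries (adjusted p up to 0.0646). Of 24 fatty acid genes, 7 fell and 3 rose (14 adjusted over the list alone). Fasn, the fatty acid synthase, fell 1.2-fold, Cpt1a 1.23-fold and Acly 1.14-fold, while Lpl rose 4.97-fold, and Cd36 and Acsl1, named after their values were seen, rose too. The adipocyte list was higher in the same knockout libraries (difference 1.91 in mean log2 CPM). The fatty acid list had a median change of -0.07 and a mean of 0.20, and its camera direction was down (adjusted p = 0.179).

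Some genes of translation and of mitochondria rose slightly, and most did not pass. Of 38 ribosomal protein genes, 12 rose and 26 did not pass (18 adjusted over the list alone). Rpl10a rose 1.41-fold, from 189 ± 3.65 to 267 ± 8.63 CPM, Rps27 1.26-fold, Rps24 1.21-fold and Rps20 1.19-fold (SD, n = 5 each); ribosomal protein genes have many pseudogene copies, so these values are uncertain. The list was higher by camera (adjusted p = 1.43e-06; adjusted p = 0.737 with an estimated correlation). Of 12 mitochondrially encoded genes, mt-Atp8 (1.24-fold), mt-Nd6 (1.22-fold), mt-Nd5 (1.2-fold) and mt-Co1 (1.15-fold) rose (7 adjusted over the list alone; camera adjusted p = 0.000793, adjusted p = 0.737 with an estimated correlation). Without knockout libraries 9 and 10 the calls of mt-Nd6, mt-Nd5 and mt-Co1 were lost, with fewer samples and changes nearly as large (log2 fold change 0.25, 0.21 and 0.16, against 0.28, 0.26 and 0.20 in all libraries). With the adipocyte value of each library as a covariate, chosen after seeing the data, these 3 and mt-Atp8 lost their calls. Over all alternatives, the lowest log2 fold changes of mt-Atp8, mt-Nd6, mt-Nd5 and mt-Co1 were 0.149, 0.125, 0.092 and 0.093. Of 26 proliferation genes, Ccnb1 (1.22-fold), Birc5 (1.2-fold) and Cdc20 (1.17-fold), all of mitosis, rose (3 adjusted over the list alone; camera adjusted p = 0.0116, adjusted p = 0.795 with an estimated correlation). Of 24 p53 response and apoptosis genes, Cdkn1a (1.44-fold), Apaf1 (1.14-fold) and Perp, the last named after its values were seen, rose, and Sesn2 (1.35-fold) and Bak1 (1.24-fold) fell (5 adjusted over the list alone). Of 19 immediate-early and heat shock genes, Hspa1a (1.45-fold), Hspb1 (1.30-fold) and Jun (1.25-fold) fell (4 adjusted over the list alone; camera adjusted p = 0.0224, adjusted p = 0.737 with an estimated correlation). Hspa1a has a near-identical copy and is uncertain. Of 21 interferon response genes, 1 rose and 2 fell (4 adjusted over the list alone), among them Bst2, which rose 1.30-fold, and Ifih1, which fell 1.31-fold. When single libraries were left out, Ifih1 lost its edgeR call in 9 fits and Apaf1, Jun, Hspb1 and mt-Co1 in 7 each. Cdc20 lost its call in 6, Birc5 in 5 and mt-Nd5 in 1.

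The design also asked whether changed genes gathered around the targeted locus or on particular chromosomes. Within 20 Mb of Nr1h4 on chromosome 10, 48 of 353 tested genes changed (13.6%), against 13.9% elsewhere (Fisher's exact odds ratio 0.976, two-sided p = 0.938). Within 5 Mb, 14 of 75 genes changed (18.7%, two-sided Fisher's exact p = 0.24), among them Usp44 and Apaf1. Windows of 10 Mb were tested after the main results were seen. The window from 90 to 100 Mb, beside Nr1h4, held 14 changed genes of 47 (one-sided Fisher's exact p = 0.00365, adjusted over the windows 0.0911). On chromosome 17, 178 of 877 tested genes changed (20.3%), and on chromosome 3, 165 of 841 (19.6%), against 13.6% of genes elsewhere for each (one-sided Fisher's exact test, p adjusted over the chromosomes 1.24e-06 and 1.76e-05). No other chromosome passed, and the next was chromosome 8 with 153 of 957 genes (16.0%, adjusted p = 0.231). Chromosomes 3 and 17 together held 343 changed genes, where 227.8 would be found at the rate of the other chromosomes. On chromosome 17, the changed genes included Abca17, Guca1b, Dynlt1a, Rpl10a, Pou5f1, Acat2, Cdkn1a, Bak1 and Hspa1a. On chromosome 3, besides the genes with the largest changes, they included Ccna1, Sohlh2, Vcam1, Hsd3b1, Rps27, Ctss and Car3. Ccna1 and Sohlh2 start at 55045469 and 55182028 on chromosome 3, so their calls in separate germ cell lists may not be independent. Changed genes of chromosome 3 ran both ways, with 73 higher and 92 lower, as did those of chromosome 17, with 79 higher and 99 lower.

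**Figure D4:**
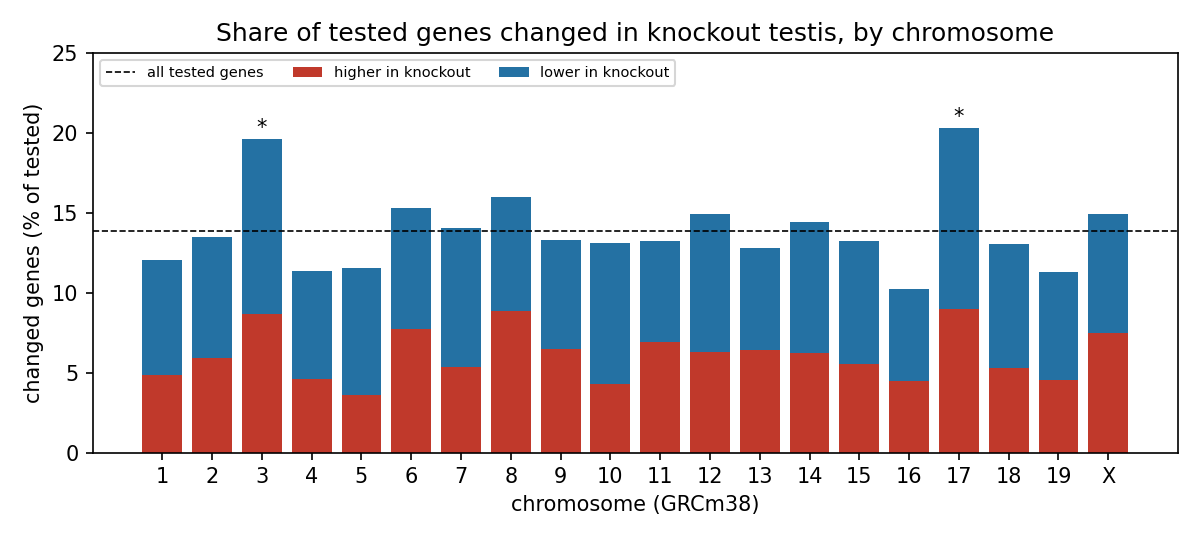
Share of tested genes that changed on each chromosome, in percent, split into genes higher (red) and lower (blue) in knockout, with a dashed line at the share over all tested genes (13.9%). Asterisks mark chromosomes 3 (19.6%) and 17 (20.3%), which passed the one-sided Fisher's exact test after adjustment.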

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

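The test of neighbouring changed pairs on chromosomes 3 and 17 and both tests of equal change among Sertoli genes were chosen after the results they measure had been seen, and the other tests of this part before. Dixon's test compared the most extreme of the 5 libraries of a genotype with the others, for named genes, list values and library measures, and 12 of 282 sets crossed its 95% limit, where chance gives 14.1.

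Of these 12, 6 were knockout library 8. On the log2 CPM scale, knockout library 8 stood apart in Abca17 (1.63, others -1.81 to -1.02), Meig1 (1.54, others 2.06 to 2.20), Cst9 (7.82, others 8.37 to 8.54), Clu (10.1, others 10.7 to 10.8), Myl9 (7.70, others 7.52 to 7.57) and Srebf2 (7.99, others 7.70 to 7.78). Knockout library 10 stood apart in Clgn (3.63, others 3.80 to 3.85) and Dhh (7.30, others 6.98 to 7.06), and knockout library 9 in Rgs5 (6.69, others 5.94 to 6.05). Among wild-type libraries, number 9 was high in Nr1h4 (-0.25, others -1.11 to -0.98), number 3 low in Pou5f1 (2.12, others 2.63 to 2.69) and number 6 high in Bst2 (4.48, others 4.19 to 4.23).

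Other splits of the 10 libraries into 5 and 5 tested whether chance alone could give the main counts. Of 100 splits, 1, the real one, gave as many changed genes, with 2576 genes against at most 4 in any other. This argues against chance alone for the number of genes. It cannot exclude chance, because every other split mixes the genotypes, which widens the spread within its groups and lowers its count. For lists called by camera at the preset correlation, 39 of the 100 splits gave as many as the real 12, with up to 20 in another, so chance cannot be excluded for the number of lists.

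Changed genes gathered on chromosomes 3 and 17. Greater depth of these genes is argued against, since within 10 strata of expression the odds of change were still 1.62 times those of other chromosomes (95% interval 1.43 to 1.84). Strain haplotypes that differ between the lines remain a candidate explanation. On these chromosomes 84 pairs of neighbouring tested genes had both changed. The median was 68 in 10000 shuffles within the chromosome (upper end of the 95% range 81, permutation p = 0.0115). Co-regulation of neighbouring genes also stays open. Of the 84 pairs, 67.9% moved the same way, against 50.0% in shuffles of the signs (upper end of the 95% range 60.7%, permutation p = 8e-04). Neither count was made on other chromosomes, where some windows of 10 Mb also held an excess of changed genes. The counts therefore do not tell why chromosomes 3 and 17 stand out. An effect of FXRα on genes of these chromosomes was not tested separately and stays open.

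Many markers of fat and of ductal epithelium were higher in knockout testis. Fat carried along with some testes may explain the adipocyte genes. Their deviations from the genotype means moved together over the libraries, with a median pairwise correlation of 0.861 (upper end of the 95% range of random lists of expressed genes 0.226). Genes of 1 cell type can move together wherever its cells lie, so this does not tell carried-along fat from fat cells that differ with genotype. The correlation estimated by camera was also high in the meiotic prophase list (0.734, against 0.905 in the adipocyte list). In wild type too, 12 of the 14 tested adipocyte genes were at 1 CPM or more. For duct epithelium carried along, the median pairwise correlation was 0.34 in the epididymis and rete testis list, over 12 genes with a mean of at least 1 CPM. This lay between the bounds of 0.5 and 0.2 set for and against it, so tissue carried along and expression within the testis cannot be told apart for this list. Of its 13 tested genes, 10 were at 1 CPM or more in wild type. The most abundant of its genes in knockout, named after their values were seen, were Epcam (70.6 ± 11.2 CPM), Crisp1 (41.6 ± 19.2) and Cdh16 (36.7 ± 15.5) (SD, n = 5 each). A change in these cells with the loss of FXRα stays open for both lists.

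Several Sertoli cell genes were lower in knockout testis, and most did not pass. The changes of 32 members (Cst9 left out) ran from -1.02 in Rhox5 to 0.75 in Trf, a wider spread than their standard errors allow (Cochran's Q = 104.7). An exact permutation test run afterwards, which takes each library's mean over the members off and does not rely on those standard errors, gave p = 0.0714 over 252 assignments, judged against bounds set after this value was seen, so a lower share of Sertoli cells as the cause of these falls, other than the rise of Cst9, cannot be told apart from changes in single genes with 5 mice per genotype. For testes further along in development, Spearman's rho was taken over the 33 members, between each gene's slope on the meiotic list within wild type and its change in knockout. It was -0.00301 (permutation p = 0.988). A rho that is not positive had been set beforehand as a result against this explanation, and the value only just met that bound. The bootstrap 95% interval, which was not part of that bound, was -0.386 to 0.41 and too wide to decide, so the explanation stays open. A change of expression within Sertoli cells lacking FXRα was not tested and stays open.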

How the results depend on the processing

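The alternatives without knockout libraries 9 and 10, with list values as covariates and without chromosomes 3 and 17 were chosen after seeing the data. No paired analysis was possible because the titles of the wild-type and knockout mice share only the number 9. The 2576 changed genes became 880 at an adjusted p under 0.01, 4024 under 0.1 and 718 with at least a 1.5-fold change, and 1427 to 2867 without 1 library, where fewer samples enter (1601 without wild-type 4, 1427 without knockout 11, 1635 without knockout 12). Other scalings, tests and filters gave 2293 to 3785, and 2466 were changed without knockout libraries 9 and 10, of which 1945 also were in the main test. With the adipocyte value of each library as a covariate, 1404 genes passed, and with the epididymis and rete testis value, which itself separates the genotypes, 60 did, 59 of them among the 2576. Among the genes given in the text, Rxfp1, Slc39a8, Tmod4, Crxos, Pianp, Shisa7, Olfml3, Lair1 and Zfp872 kept their calls under that covariate.

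Nr1h4 stayed lower throughout but lost its call under DESeq2 (-0.86, adjusted p = 0.0658), with no filter on low counts (-0.84, adjusted p = 0.0580), without knockout libraries 9 and 10 (-0.79), with the adipocyte covariate (-0.57), with the duct covariate (-0.33) and in 7 of 10 fits without 1 library (-0.92 to -0.62, adjusted p up to 0.117 without wild-type 9). Its depth of 8 to 26 counts limits this gene. The 12 lists called by camera became 0 with estimated correlations and 2 by fry, and 9 to 16 without 1 library. Genotypes did not overlap in 97.0% of genes at an adjusted p under 0.01. Near Nr1h4, the odds ratio of 0.976 at 20 Mb turned to 1.43 at 5 Mb (Fisher's exact p = 0.24), with neither past the test. The list test over mice, which a list on its own could not pass, stayed at 0, and chromosomes 3 and 17 held with DESeq2 and at 0.1.

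Of 105 changed genes picked by the naming rule besides Nr1h4, 77 kept their call in every fit without 1 library, and 85 without knockout libraries 9 and 10. All 105 were picked from the same main fit, so these shares do not stand for all changed genes. Besides those named above, Upp1, Mael, Zpbp, Meig1, Car3 and Adipoq lost their calls in some fits without 1 library. Of all 107 genes picked by the rule besides Nr1h4, changed or not, 43 lost a call with the adipocyte covariate. With the duct covariate 92 lost a call with their sign kept, 5 turned in sign and 10 stayed the same. Genes that turned in sign are not counted among the 92, although Slc51a lost its call too. Without knockout libraries 9 and 10, calls that had held in every fit without 1 library were lost in Tshr (log2 fold change 1.70 against 2.99) and Retn (1.76 against 3.28), and, with changes nearly as large and fewer samples, in Myl9 (-0.19 against -0.21), Osr2 (-0.28 against -0.32) and mt-Nd6 (0.25 against 0.28). Signs turned in Tex15, which had not passed, without wild-type 4 (-0.05), wild-type 3 (-0.13) and knockout 12 (-0.13; range without 1 library -0.13 to 0.21) and with the duct covariate (-0.088), and with that covariate in Ros1 (-0.14), Stag3 (-0.027), Slc51a (-0.084) and Cldn3 (-0.20). The cause of these changes was not tested.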

Other observations

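The tests of Gene Ontology terms, of 10 Mb windows, of pseudogenes and of the chromosomes of the named genes were all chosen after the main results were seen, and the genes named here were chosen after their values were seen. Beyond the fixed lists, genes higher in knockout testis included several homeobox genes, claudins and genes of signalling by the transmitter GABA. Of 48 tested genes of embryonic skeletal system morphogenesis, 13 rose (adjusted p = 0.00539, one-sided Fisher's exact test), 12 of them of the Hoxa and Hoxb clusters, which set positional identity along the body axis. Hoxa5 rose 3.05-fold from 0.896 ± 0.309 to 2.74 ± 1.10 CPM and Hoxb4 1.71-fold from 1.94 ± 0.1 to 3.32 ± 0.487 CPM (SD, n = 5 each). Of 17 genes of calcium-independent cell adhesion, 7 rose (adjusted p = 0.0198, Fisher's exact test), all of them claudins, such as Cldn4 (2.54-fold), Cldn7 (1.86-fold) and Cldn8 (3.33-fold). The epididymis and rete testis list, with keratins and Epcam, was higher in the same libraries (difference 1.04 in mean log2 CPM). Of 19 genes of GABA signalling, 8 rose (adjusted p = 0.00606, Fisher's exact test). The translation term held 34 risers among 170 genes (adjusted p = 3.27e-06, Fisher's exact test), nearly all ribosomal protein genes, in the direction of the ribosomal protein list.

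Among lower genes, 21 of 89 genes of male gonad development fell (adjusted p = 0.0161, one-sided Fisher's exact test), among them the Sertoli and gonadal transcription factor genes Sox9, Sox8, Wt1, Nr5a1, Nr0b1 and Gata6. Gata6 fell 1.25-fold, from 70.0 ± 8.33 to 55.8 ± 6.44 CPM (SD, n = 5 each). Of 11 genes of beta-amyloid metabolism, 7 fell (adjusted p = 0.0161, Fisher's exact test), including the peptidase genes Mme, from 193 ± 20.1 to 68.7 ± 5.45 CPM, and Ide, from 196 ± 8.03 to 117 ± 24.3 CPM (SD, n = 5 each). These tests treat genes as independent, which neighbouring and co-expressed genes are not.

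The largest fitted changes fell on gene copies. Of the 25 changed genes with a fitted change of at least 32-fold, 19 were pseudogenes (76%), against 2.85% of the other tested genes (Fisher's exact p = 9.5e-25). Of the other 6, 5 were numbered gene models and 1 was Rxfp1. In 4 of the 25, a genotype had no count in any library, so that their fitted change is no bound, and 21 were still at least 32-fold apart when such a group was set to 3 counts per library. In 24 of the 25 the genotypes did not overlap. Gm13394, a pseudogene on chromosome 2, stood at 0.0421 CPM in wild type and 20.98 CPM in knockout, and the pseudogene Gm7148 on chromosome 17 at 2.33 and 0.00514 CPM.

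Along the genome, 6 of 275 windows of 10 Mb held an excess of changed genes (one-sided Fisher's exact test, adjusted over the windows). They were chromosome 8 from 70 to 80 Mb (42 of 132 genes, adjusted p = 2.7e-05), chromosome 17 from 0 to 10 Mb (19 of 47, adjusted p = 0.000924) and from 20 to 30 Mb (55 of 226, adjusted p = 0.00154), chromosome 6 from 50 to 60 Mb (22 of 70, adjusted p = 0.00887), chromosome 7 from 0 to 10 Mb (24 of 88, adjusted p = 0.0386) and chromosome 2 from 170 to 180 Mb (23 of 85, adjusted p = 0.0463). No window of chromosome 3 passed, although 8 of the 24 genes with the largest named changes lie on it. Of these 8 genes, 6 rose and 2 fell. Against 14058 tested genes with a mean of at least 1 CPM and no model or pseudogene name, Fisher's exact p was 8.05e-06. That background was not limited to changed genes without overlap, so this p-value also counts the excess of changed genes on chromosome 3.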
